A study of Mus musculus with 6 samples.

How the data were processed

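Total RNA was measured on 6 single-colour microarrays with biotin-labelled cDNA. The cells were primary keratinocytes of CD1 mice, grown in low-calcium medium and infected with a retrovirus. In 3 cultures the virus encoded caNFATc1, a human NFATc1 made constitutively active by mutations in its autoinhibitory domain. In 3 vector control cultures the virus was the empty MSCV vector. The groups and the replicate numbers come from the sample titles.

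The authors deposited 1 table of log2 values, with 28815 rows and a column per array. RMA (robust multi-array average) and the genome build mm8 are named per the submitters' processing notes. The software, its version and any filter on rows are not given in the sources used here. The median of every row over the 6 arrays was 0 within 1e-06, so the deposited values are relative to each row's own median. Differences between arrays are therefore kept, while the brightness of a row is not. No row could be called dim, no level is reported for any gene, and the 2 filters on dim rows that had been planned could not be run. The base of the logarithm was taken to be 2 because RMA gives log2 values. Values ran from -6.05 to 4.03, and the medians of the 6 arrays lay between -0.01 and 0.02. Scanner signals were not used here, so the precision is limited by the number of arrays.

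Rows were named through the platform annotation table, in which 21780 rows carried 1 gene symbol, 1605 carried several and 5430 were not listed. Symbols were looked up by Entrez number in a table of the GRCm38.p6 assembly. No symbol changed, and the 91 rows whose number was not found kept the annotation's symbol. Because the arrays' build differs from that assembly, no coordinates are given. The 21780 rows with 1 symbol gave 19935 genes, of which 998 had several rows. The rule first written was to take the row with the highest mean. In row-centred values the mean no longer follows brightness, so the mean of a gene's rows was used, which had been planned as an alternative. The original rule is among the alternatives. The Sprr2, Lce and Stfa families and some other genes have near-identical copies whose probes can share signal.

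The 2 groups were compared with limma (version 3.58.1, R 4.3.3), using lmFit and eBayes with group as the only term, 2-sided, and a Benjamini-Hochberg adjusted p under 0.05 over the 19935 genes. Differences are caNFATc1 minus vector control on the log2 scale, with limma's moderated standard error (SE) and 3 arrays per group. The p-values measure the spread between these samples. The series design calls the replicates biological but does not say that equal numbers share a culture. The pairing was decided by a limit of 0.1 on the correlation, set before the data were examined. The deviations of same-numbered arrays from their group means correlated across genes at 0.71 for replicate 1, 0.61 for replicate 2 and 0.57 for replicate 3, while the 6 other pairings lay between -0.60 and 0.18. All 3 exceeded the limit, so the numbers were taken to pair the arrays. The fit with the replicate number as a block had been planned as an alternative. Its list values are given beside those of the unblocked fit where the call of a list changes. Its counts of calls are given where they move by over 1.5 times. The words "with the replicate block" mark both. The replicate block fit estimates the same log2 differences with another SE. Brackets after a gene said to rise or fall with the block give its log2 difference ± SE and its adjusted p in that fit. For most of these genes the unblocked value is not printed, and it can be far weaker. Lce1f and Gsta3 had limma adjusted p = 0.528 and 0.551 without the block (SE 0.74 and 0.79), and their arrays overlapped between groups. Calls made only with the block rest on the pairing of the arrays.

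The 33 gene lists and the rules for naming genes were fixed before the data were examined, from textbook knowledge. Of their 926 genes, 856 were measured, after 6 older symbols were matched by hand. Lists were tested with camera (inter-gene correlation preset to 0.01) and adjusted over the 33 lists. Counts of members are given over all genes and adjusted over the list alone. The genes named were the 12 with the largest rise and the 12 with the largest fall among those past the test with no overlap between groups, leaving out predicted genes and clone names, of which 1 passed without the block and 28 with it. Up to 4 members of each list with the lowest p, and 11 fixed genes, were also named. Of the 11, 9 had a row of their own and 2, Cdkn1a and Prlr, were not analysed here. After the data were seen, the first rule was also applied to the fit with the replicate block, and 47 genes were named because their values had been seen. These were Gsta3, Cbr2, Lce1f, Zfp750, Krt6b, Acp5, Grhl3, Acaca, Fasn, Insig1, Srebf2, Trps1, Fosl1, Bmpr1b, Rnf43, Lox, Zeb2, Tnc, Vdr, Npnt, Cyp2s1, Mgst2, Sult2b1, Abcg2, Gpx2, Osgin1, Cxcl14, Atf3, Dusp1, Pfkl, Itga6, Itgb4 and Lamb3 among the lists, Atp6v1e1, Atp6ap2, Lsm2, Nup37, Nop58, Mtmr11 and Rab43 among families of symbols, and the fibroblast transcripts Col1a1, Col1a2, Vim, Sparc, Dcn, Lum and Thy1.

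The alternatives were a second quantile normalization, centring of each array, all rows tested singly, the highest row per gene, an eBayes trend with robust settings, array weights, a plain equal-variance test, the replicate block, each array left out in turn, an estimated inter-gene correlation, the fry rotation test and other thresholds. Chosen after seeing the data were the fits without replicate 1, 2 or 3 of both groups, the block with an estimated correlation and the block at a stricter threshold. On values simulated from the 19935 genes of this comparison, with 100 genes changed by 1 and 100 by 2 log2 units, the unblocked fit recovered 81% and 97% with 0 false calls. The fit with the replicate block recovered 99% and 100%, with 10 false calls. The simulated pair effects and residual spread came from the replicate block fit, the changed genes were picked at random, and noise was independent between genes. The simulation therefore cannot choose between the fits, and recovery in the real data may be lower.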

Results

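The transcriptomes of 6 cultures of primary mouse keratinocytes were measured, 3 infected with a retrovirus carrying constitutively active human NFATc1 (caNFATc1) and 3 with the empty vector. NFATc1 is a transcription factor that the calcium-dependent phosphatase calcineurin sends to the nucleus, and the caNFATc1 form does not need that step. The comparison asks which keratinocyte transcripts differ when NFATc1 is active. The deposited log2 values are relative to each row's median over the 6 arrays, so the results are differences between groups and not levels, and the number of arrays limits their precision. Arrays with the same replicate number deviated together in both groups. Replicate 1 stood apart: Xist, the RNA that coats the inactive X chromosome, was lower there than in replicates 2 and 3 by at least 5.97 log2 units, and the Y-linked gene Eif2s3y was higher by at least 2.99. Between the groups, Xist differed by -0.03 ± 0.07 (SE with the replicate block, n = 3 pairs). In replicate 1 the Y-linked genes Uty, Eif2s3y and Kdm5d were higher in caNFATc1 cells by 1.38, 0.77 and 0.31. In pairs 2 and 3 they differed by between -0.04 and 0.10. Over all pairs they passed neither fit, which cannot speak to the difference within pair 1.

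The mouse counterpart of the transgene and known NFAT targets were examined first. The row for mouse Nfatc1 differed by 0.04 ± 0.09 (SE, n = 3 per group, limma adjusted p = 0.917), with differences of 0.12, 0.10 and -0.10 in the 3 same-numbered pairs. The transgene is human, so mouse probes may see it only in part. Whether this row detects it was not tested, so the row does not check the labels. Rcan1, a known NFAT target that encodes an inhibitor of calcineurin, rose 10.4-fold in caNFATc1 cells (log2 difference 3.38 ± 0.19, adjusted p = 0.0113), by 3.61, 3.12 and 3.40 in the 3 pairs. Of 24 measured calcineurin-NFAT pathway parts, Rcan1 rose over all genes, 3 rose when adjusted over the list alone (4 rose and 1 fell with the replicate block), and over all genes with the block 3 rose and 1 fell. Orai1, the pore of the store-operated calcium channel, rose by 1.10 ± 0.07 (adjusted p = 0.00479 with the block), the kinase gene Dyrk2 rose by 0.67 ± 0.06 (0.00904), and Nfatc2 fell by 0.76 ± 0.10 (0.0168). The list's median difference was 0.05, its mean, which includes Rcan1, was 0.25, and 16 members were positive and 8 negative. The list was called upward (camera adjusted p = 0.0142), a call lost with an estimated correlation (adjusted p = 0.468).

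NFAT target genes known from other cells were not called as a group by camera (26 measured, adjusted p = 0.643). The fry test for change in either direction called the list (adjusted p = 0.0019, and 0.00905 with the replicate block). Rcan1 rose over all genes and 2 members rose when adjusted over the list alone (4 rose and 1 fell with the replicate block). With the replicate block Rcan1 and the cytokine gene Tnf rose and the phosphatase gene Acp5 fell. Tnf rose by 1.13 ± 0.13 (adjusted p = 0.0154 with the block, 0.118 without) and Acp5 fell by 0.43 ± 0.07 (0.0349 with the block). The nuclear receptor genes Nr4a1 and Nr4a3 differed by 1.35 and 0.26 and passed neither fit (0.0593 and 0.116 with the block). The list's median difference was -0.03, its mean 0.17 and the direction of its test upward.

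**Figure D1:**
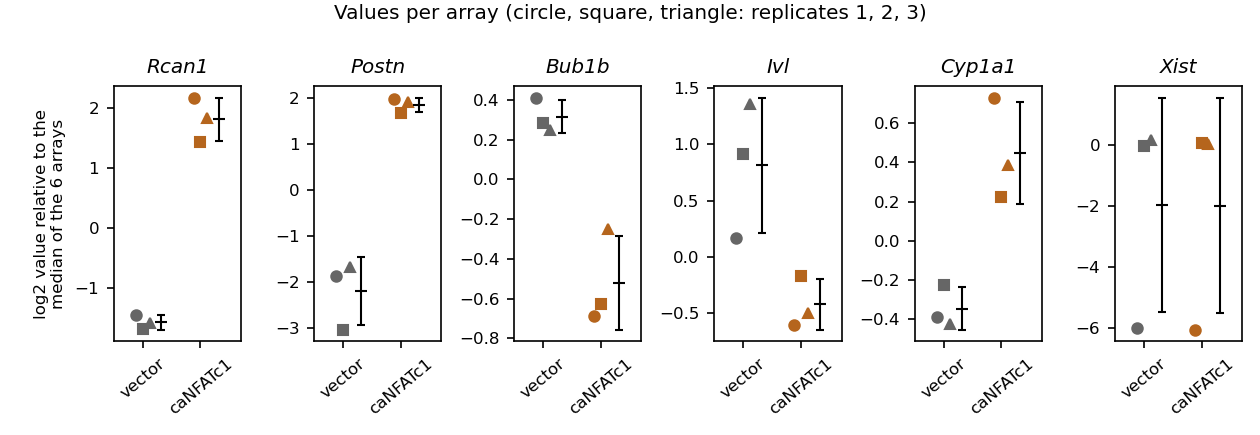
Values per array for 6 genes on the log2 scale, relative to each gene's median over the 6 arrays, with the mean and SD of the 3 arrays of each group. Rcan1 and Postn are higher in all 3 caNFATc1 arrays, by 3.38 and 4.05 on average, while Xist separates replicate 1 from replicates 2 and 3 in both groups.

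Across 19935 genes, 41 were higher and 2 lower in caNFATc1 cells, and 29 of the 41 and 1 of the 2 differed at least 2-fold. Fmod (fibromodulin, a collagen-binding proteoglycan) rose 23.6-fold, with a log2 difference of 4.56 ± 0.35 and an adjusted p of 0.021. Olr1, a scavenger receptor for oxidised lipoprotein, rose 20.5-fold (4.36 ± 0.27, adjusted p = 0.0128). Postn, which encodes the matrix protein periostin, rose 16.5-fold (4.05 ± 0.36, adjusted p = 0.0276). Atp1b1, a subunit of the sodium-potassium pump, rose 13.7-fold (3.78 ± 0.15, adjusted p = 0.00478), and the lysyl oxidase family member Loxl3 rose 7.77-fold (2.96 ± 0.17, adjusted p = 0.0113). The imprinted zinc finger gene Peg3, the nucleoside transporter gene Slc29a1, Zfp185, the semaphorin receptor gene Plxna2, Slc43a3 and Mrgprf rose by between 1.58 and 2.12. The genes that fell were the adhesion receptor gene Adgrf4, by 1.09 ± 0.12 (adjusted p = 0.0434), and Vamp5, by 0.63 ± 0.07 (adjusted p = 0.046). The count of the unblocked fit, which does not use the pairing, depended on single arrays. Without vector control replicate 1, 2 or 3 limma called 6, 2 and 0 genes. Without caNFATc1 replicate 1, 2 or 3 it called 19, 83 and 2. In the setting with 0 calls, 2113 genes had an unadjusted p under 0.05. Each of these settings also breaks a same-numbered pair, and counts with whole pairs left out are given below. The plain equal-variance test called 0, with 2125 genes at an unadjusted p under 0.05.

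With the replicate block, 744 genes were higher and 475 lower, 158 and 32 of them at least 2-fold, and all 43 genes of the unblocked fit were among them. The naming rule, applied to this fit after the data were seen, added Egfl6 (log2 difference 4.20 ± 0.42, adjusted p = 0.00983 with the block), Tmem45b (3.14 ± 0.18, 0.00382), the receptor kinase gene Grk5 (2.88 ± 0.23, 0.00604), the growth factor gene Igf2 (2.84 ± 0.27, 0.00934), Srpx2 (2.78 ± 0.08, 6.58e-04) and Fxyd5, a regulator of the sodium-potassium pump (2.71 ± 0.09, 0.00105). The falling genes it added were the pseudogene Sprr2j-ps, Orm1, the chemokine gene Cxcl5, Vnn1, Cpn1, the fatty acid binding protein gene Fabp5, Ivl (involucrin, a cornified envelope precursor), Cwh43, Fras1, Tmprss11b and Igfbp3, with log2 differences between -1.94 and -1.09. Cxcl5 fell by 1.31 ± 0.11 (adjusted p = 0.00639 with the block) and Fabp5 by 1.26 ± 0.10 (0.00605). Without replicate 1, 2 or 3 of both groups, the unblocked fit gave 31, 2 and 0 genes higher and 0 lower each time, with 2838, 1587 and 1580 at an unadjusted p under 0.05 by limma. With the block these settings gave 509, 513 and 605 higher and 202, 230 and 481 lower.

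**Figure D2:**
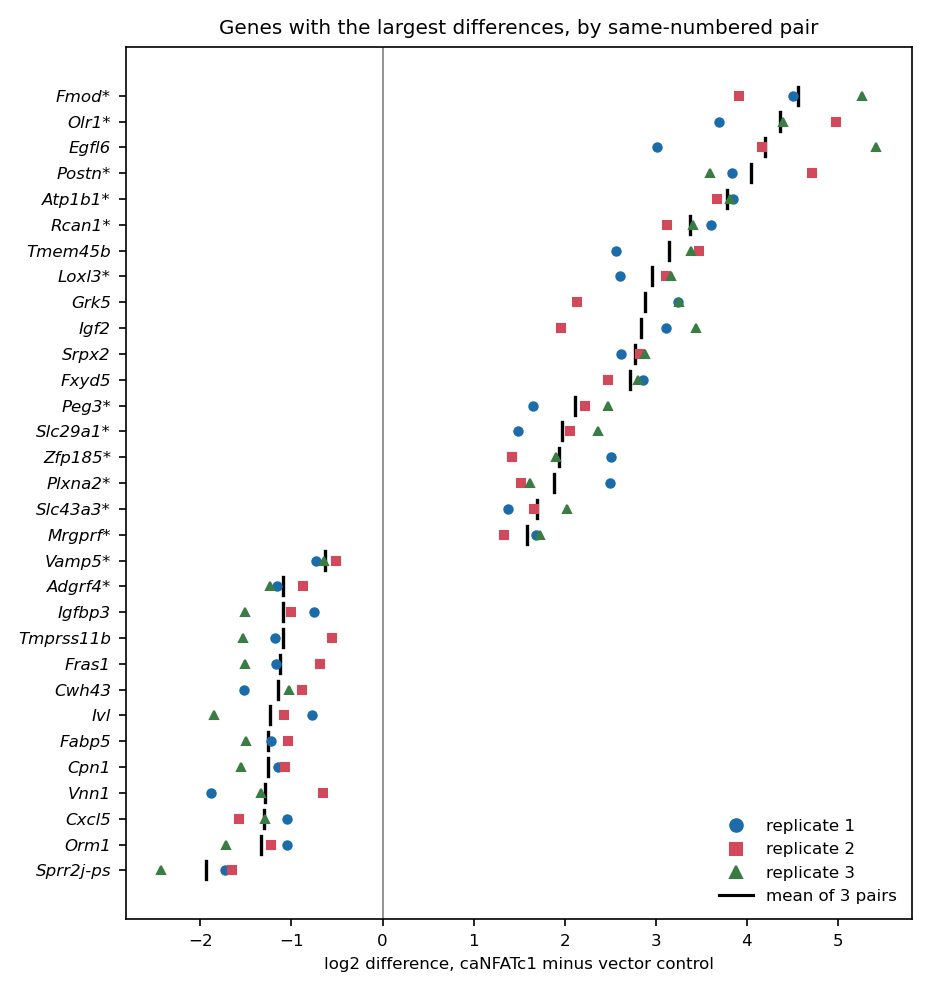
Log2 difference, caNFATc1 minus vector control, within each same-numbered pair (coloured symbols) and their mean (black tick) for the genes named by size of change. A star marks an adjusted p under 0.05 in the unblocked fit; the means run from 4.56 for Fmod to -1.94 for Sprr2j-ps.

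Genes of cell division were lower in caNFATc1 cells. Of 39 measured genes of G2/M and mitosis, 38 had a negative difference and the median was -0.62. Of these, 34 fell when adjusted over the list alone (37 with the replicate block) and 15 fell over all genes with the block. The spindle checkpoint genes Ttk and Bub1b fell by 0.94 ± 0.13 and 0.84 ± 0.12 (adjusted p = 0.0203 and 0.024 with the block), and the centriole kinase gene Plk4 and Cks2 fell by 0.62 ± 0.11 and 0.58 ± 0.08 (0.0347 and 0.0203). Of 43 genes of G1/S and DNA replication, 40 had a negative difference and the median was -0.53. In this list 11 fell when adjusted over the list alone (30 with the block) and 12 fell over all genes with the block, among them the helicase subunit gene Mcm5 (-0.75 ± 0.14, 0.044), Tyms (-0.80 ± 0.13, 0.031), Cdc6 (-0.64 ± 0.10, 0.028) and Rfc4 (-0.53 ± 0.09, 0.0334). The cyclin gene Ccnd1 and Cdk4 differed by -0.41 ± 0.18 and -0.12 ± 0.06 and passed neither fit (adjusted p = 0.267 and 0.341 with the block). The median difference of the mitosis list was -0.79, -0.84 and -0.23 in pairs 1, 2 and 3, and that of the G1/S list was -0.75, -0.58 and -0.17. Both lists lay below other genes (camera adjusted p = 1.59e-21 and 1.29e-13), calls that were lost with an estimated correlation (adjusted p = 0.468 for both).

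DNA repair genes lay lower as a list. Of 44 measured, 32 had a negative difference and the median was -0.20. Limma called 0 adjusted over the list alone (17 at an unadjusted p under 0.05), against 5 higher and 17 lower with the replicate block. Over all genes 7 fell with the block, among them the helicase gene Blm (-0.71 ± 0.10, 0.0203) and the recombination gene Rad51b (-0.57 ± 0.10, 0.037). The checkpoint kinase gene Chek1 and Pms2 differed by -0.80 and -0.34 and did not pass (0.063 and 0.0638 with the block). The list was called (camera adjusted p = 0.00182) but not with an estimated correlation (adjusted p = 0.471). Of 856 listed genes measured, Rcan1 and Postn passed the unblocked limma fit over all genes, 187 had an unadjusted p under 0.05, and 134 passed with the block. Among 32 measured CDK inhibitors and p53 targets, limma called 0 with or without the block, over all genes and adjusted over the list alone, with 4 and 2 at an unadjusted p under 0.05 (camera adjusted p = 0.628), and Gadd45g and Cdkn2b differed by -0.55 and -0.24. The CDK inhibitor gene Cdkn1a had no row of its own, so it was not among them and its change is unknown here.

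Genes of late epidermal differentiation lay lower as a list. Of 43 measured genes of the cornified envelope and granular layer, 36 had a negative difference and the median was -0.18. The list includes Lce genes, whose near-identical copies can share probe signal, so these counts may not be of independent genes. Limma called 0 adjusted over the list alone (5 at an unadjusted p under 0.05), against 1 higher and 11 lower with the replicate block, and 8 fell over all genes with the block. The ceramide synthase gene Cers3 fell by 0.92 ± 0.07 (adjusted p = 0.00604 with the block), the cross-linking enzyme gene Tgm1 by 0.64 ± 0.10 (0.0263) and Lce1f by 1.38 ± 0.11 (0.00617, and 0.528 without the block), while Lce1g and Cst6 differed by -0.24 and 0.83 without passing. The camera call (adjusted p = 0.00404) was lost with an estimated correlation (adjusted p = 0.824) and without vector control replicate 2 (0.199). Of 24 spinous genes, 1 rose and 1 fell when adjusted over the list alone (4 rose and 9 fell with the block). Over all genes, members that fell with the block included Ivl (-1.24 ± 0.20, 0.03), Elovl4, which makes very long fatty acids (-1.02 ± 0.11, 0.011), and the transcription factor genes Zfp750 (-1.23 ± 0.16, 0.0169) and Grhl3 (-0.96 ± 0.13, 0.019). The Notch ligand gene Jag1 rose (1.06 ± 0.19, 0.039). The spinous list passed with the block (camera adjusted p = 0.0421, against 0.124 without), and not with the block and an estimated correlation (adjusted p = 0.798). Krt10 and Krt14, keratins of the spinous and basal layers, differed by -0.10 ± 0.07 and -0.02 ± 0.06 and passed neither fit (0.474 and 0.934 with the block).

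Of 27 fatty acid and sebaceous genes, 21 had a negative difference, 1 fell when adjusted over the list alone (1 rose and 5 fell with the replicate block), and over all genes with the block Fabp5, the triglyceride synthesis gene Dgat2 (-0.75 ± 0.07, 0.00859), Fasn and Acaca fell. Pparg and Plin5 differed by 0.38 and -0.15 without passing. The list's call (camera adjusted p = 0.0366) was lost with an estimated correlation (adjusted p = 0.468), without vector control replicate 2 or 3 (0.0847 and 0.0994), without caNFATc1 replicate 2 (0.0669) and without replicate 2 of both groups (0.0708). Of 20 cholesterol synthesis genes, limma called 0 adjusted over the list alone (2 at an unadjusted p under 0.05), against 1 higher and 11 lower with the block. Over all genes the lanosterol synthase gene Lss (-0.72 ± 0.08, 0.0117) and Insig1 (-0.49 ± 0.07, 0.0244) fell and Srebf2 (0.35 ± 0.07, 0.0452) rose with the block, while Mvk and Mvd differed by -0.37 and -0.26 without passing. That list passed with the block (camera adjusted p = 0.00117, against 0.124 without), and not with the block and an estimated correlation (adjusted p = 0.683).

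Of 24 hair shaft and inner root sheath genes, 19 had a negative difference. Limma called 0 adjusted over the list alone (5 at an unadjusted p under 0.05), against 2 higher and 3 lower with the replicate block. Over all genes with the block Foxn1, a transcription factor of hair differentiation (-0.98 ± 0.16, 0.0321), and Padi3 (-0.52 ± 0.08, 0.028) fell and Trps1 (0.81 ± 0.11, 0.0188) rose, while Dlx3 and Krt73 differed by -0.35 and -0.18 without passing. The list's camera call (adjusted p = 0.0334) was lost with the block (0.122), with an estimated correlation (adjusted p = 0.468), without replicate 1 or 2 of both groups (0.152 and 0.0637), without vector control replicate 1 or 3 (0.0573 and 0.0792) and without caNFATc1 replicate 2 (0.0956). Of 26 wound and stress keratinocyte genes, 1 rose and 1 fell when adjusted over the list alone (3 rose and 6 fell with the block). With the block, over all genes, the integrin gene Itga5 (1.58 ± 0.17, 0.0117) and Stfa3 rose and the protease inhibitor gene Slpi (-0.99 ± 0.08, 0.00604), Fosl1, Krt6b and the urokinase gene Plau (-0.53 ± 0.09, 0.0303) fell (camera adjusted p = 0.943).

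**Figure D3:**
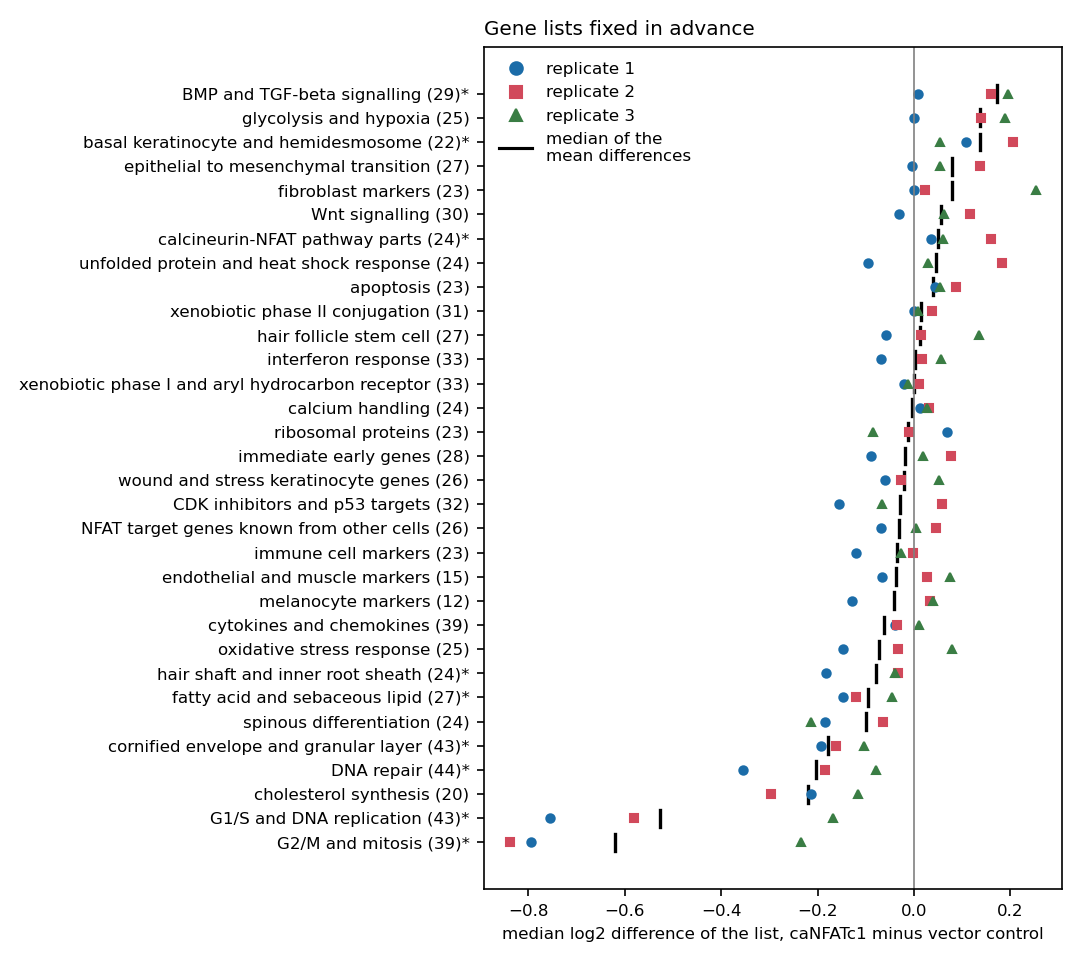
Median log2 difference, caNFATc1 minus vector control, of 32 gene lists in each same-numbered pair (coloured symbols) and of the mean differences (black tick), with the number of measured genes, the sex-linked list being left out. A star marks a camera adjusted p under 0.05 with the preset correlation; the lists of G2/M and of G1/S lie lowest, at -0.62 and -0.53.

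Basal keratinocyte and hemidesmosome genes lay higher as a list, with 14 of 22 measured genes positive and a median of 0.14. Of these, 3 rose when adjusted over the list alone (8 rose and 1 fell with the replicate block) and 7 rose over all genes with the block. The hyaluronan receptor gene Cd44 rose by 1.54 ± 0.12 (adjusted p = 0.00604 with the block), the integrin gene Itgb1 by 0.65 ± 0.08 (0.018), Cav1 by 0.47 ± 0.07 (0.0244) and Plec by 0.40 ± 0.07 (0.0347). The hemidesmosome integrin genes Itga6 and Itgb4 and the laminin gene Lamb3 differed by 0.06, -0.05 and -0.10 and passed neither fit. The camera call (adjusted p = 0.00426) was lost with an estimated correlation (adjusted p = 0.824), without vector control replicate 1 (0.120) and without caNFATc1 replicate 2 (0.0527). Of 29 BMP and TGF-beta genes, 20 were positive and 4 rose when adjusted over the list alone (7 rose and 2 fell with the block). With the block, over all genes, the activin subunit gene Inhbb (1.28 ± 0.23, 0.0363), Tgfb1 (0.61 ± 0.07, 0.0132), its receptor gene Tgfbr1 (0.52 ± 0.09, 0.0319), Bmpr2 (0.38 ± 0.07, 0.0343) and Bmpr1b rose. That camera call (adjusted p = 0.0142) was lost with an estimated correlation (adjusted p = 0.468) without vector control replicate 2 (0.0519) and without replicate 3 of both groups (0.0727).

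Wnt genes were not called as a list (30 measured, camera adjusted p = 0.393). In it 1 gene rose when adjusted over the list alone (7 rose and 1 fell with the block). With the block, over all genes, the Wnt inhibitor family member Dkk3 (1.31 ± 0.13, 0.0105), the ligand genes Wnt7b (1.09 ± 0.10, 0.00788) and Wnt6 (0.79 ± 0.12, 0.0278), the receptor gene Fzd1 (0.68 ± 0.07, 0.0102) and Rnf43 rose. Of 27 genes of the epithelial to mesenchymal transition, 2 rose when adjusted over the list alone (7 with the block). With the block, over all genes, the lysyl oxidase gene Lox (0.84 ± 0.07, 0.00604), Itga5, Tgfb1, Zeb2 (0.72 ± 0.11, 0.0293) and Prrx1 (0.43 ± 0.08, 0.0376) rose, while Epcam differed by -0.26 without passing. That list passed with the block (camera adjusted p = 0.0421, against 0.124 without), and not with the block and an estimated correlation (adjusted p = 0.683). Of 27 hair follicle stem cell genes, Postn rose over all genes and 2 rose when adjusted over the list alone (6 rose and 3 fell with the block). Over all genes with the block Postn, Ccn2 (1.53 ± 0.17, 0.0136), the transcription factor gene Tcf7l2 (1.09 ± 0.14, 0.0168), Gas1 (0.93 ± 0.16, 0.0351) and Tnc rose and Vdr and Npnt fell (camera adjusted p = 0.159).

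Markers of other cell types were read in the same cultures. Of 23 fibroblast markers, Postn rose over all genes and 3 rose when adjusted over the list alone (5 rose and 1 fell with the replicate block). Over all genes with the block Postn, Col3a1 (1.20 ± 0.19, 0.0296), Col6a1 (0.73 ± 0.10, 0.0207) and Col6a2 (0.51 ± 0.07, 0.0203) rose (camera adjusted p = 0.124, 0.0251 and 0.0453 without caNFATc1 replicate 1 or 2, and 0.0361 without replicate 2 of both groups). With an estimated correlation and all arrays the list's camera adjusted p was 0.824, and 0.762 with the block. Limma called 0 of 12 melanocyte markers with or without the block, over all genes and adjusted over the list alone, with 1 and 0 at an unadjusted p under 0.05 (camera adjusted p = 0.707), and Mitf and Gpnmb differed by 0.15 and 0.88. The melanocyte list's median and test were negative and its mean positive. Likewise 0 of 23 immune cell markers passed limma's test in any of these ways, with 1 at an unadjusted p under 0.05 in each (camera adjusted p = 0.172), and H2-Ab1 and Tyrobp differed by -0.22 and -0.17. Of 15 endothelial and muscle markers, limma called 0 adjusted over the list alone (2 at an unadjusted p under 0.05), and Esam rose over the list alone and over all genes with the block (0.43 ± 0.07, 0.0318), and the list was not called (camera adjusted p = 0.707).

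Enzymes that activate or conjugate foreign chemicals bear on the handling of carcinogens, and they were not called as a group by camera. The fry test for change in either direction called both lists with the replicate block (adjusted p = 0.014 for phase I and 0.0425 for phase II). Without the block it did not (0.068 and 0.546). With the block this test called 26 of the 33 lists, so its calls are not particular to these enzymes. Of 33 genes of phase I metabolism and the aryl hydrocarbon receptor, 1 rose when adjusted over the list alone and 4 rose and 2 fell so with the replicate block (camera adjusted p = 0.819). Over all genes with the replicate block Cyp1a1, Ephx1 and Cbr2 rose and Cyp3a13 and Cyp2s1 fell. Cyp1a1, which oxidises polycyclic aromatic hydrocarbons, rose 1.73-fold (0.79 ± 0.13, adjusted p = 0.0313 with the block, 0.0973 without), by 1.12, 0.45 and 0.81 in the 3 pairs. The epoxide hydrolase gene Ephx1 rose by 0.71 ± 0.10 (0.0204 with the block) and the carbonyl reductase gene Cbr2 by 1.02 ± 0.07 (0.00604, and 0.411 without the block), and Cyp3a13 fell by 0.50 ± 0.10 (0.0453). Cyp1b1 and Ahr differed by 0.11 ± 0.10 and 0.23 ± 0.08 and passed neither fit (0.646 and 0.168 with the block). Of 31 phase II genes (camera adjusted p = 0.658), limma called 0 adjusted over the list alone (3 at an unadjusted p under 0.05), against 5 higher and 3 lower with the block. Over all genes the glutathione transferase genes Mgst3 (1.05 ± 0.21, 0.0458) and Gstm1 (0.60 ± 0.10, 0.0338) and Abcg2 rose with the block, and Gsta3 (-1.40 ± 0.18, 0.0188, and 0.551 without the block), Sult2b1 and Mgst2 fell. Of 25 oxidative stress genes, 1 rose when adjusted over the list alone (3 rose and 3 fell with the block), and over all genes with the block Gpx1 (0.52 ± 0.09, 0.031) and Gpx2 rose and the cystine transporter gene Slc7a11 (-0.91 ± 0.10, 0.0118) and Osgin1 fell (camera adjusted p = 0.723).

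Survival and hypoxia genes included members that rose. Of 23 apoptosis genes, 3 rose when adjusted over the list alone (4 with the replicate block), and the survival genes Bcl2 (1.33 ± 0.10, 0.00604) and Bcl2l1 (0.67 ± 0.09, 0.0203) rose over all genes with the block, while Cflar and Xiap differed by 0.44 and 0.27 without passing (camera adjusted p = 0.0777). Of 25 glycolysis and hypoxia genes, limma called 0 adjusted over the list alone (4 at an unadjusted p under 0.05), against 7 higher and 1 lower with the block. Over all genes Ndrg1 (0.98 ± 0.07, 0.00596), the mitophagy gene Bnip3 (0.83 ± 0.09, 0.0111), Vegfa (0.63 ± 0.07, 0.0138), P4ha1 (0.77 ± 0.12, 0.0293) and Pfkl rose with the block. This list passed with the block (camera adjusted p = 0.00306, against 0.0537 without), and not with the block and an estimated correlation (adjusted p = 0.683).

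Cytokine, stress and early response genes moved both ways. Of 39 cytokine and chemokine genes, 2 rose and 1 fell when adjusted over the list alone (3 and 2 with the block), and over all genes with the replicate block the NF-kappa-B inhibitor gene Nfkbia (0.94 ± 0.08, 0.00715), Tnf and Cxcl14 rose and Cxcl5 and Il18 (-0.58 ± 0.08, 0.0205) fell. The list's median and test were negative and its mean positive (camera adjusted p = 0.826). Of 28 immediate early genes, 2 rose when adjusted over the list alone (8 rose and 3 fell with the block), and over all genes with the block the phosphatase genes Dusp6 (1.29 ± 0.13, 0.00983) and Dusp1, Fosl2 (0.74 ± 0.08, 0.0116) and Atf3 rose and Fosl1 (-1.04 ± 0.13, 0.0158) fell. Its median was negative, its mean positive and its test upward (camera adjusted p = 0.628). Of 33 interferon genes, limma called 0 adjusted over the list alone (1 at an unadjusted p under 0.05), against 2 higher with the block, and Isg20 (0.69 ± 0.08, 0.0123) and Ifit2 rose over all genes with the block (camera adjusted p = 0.707). With the block, among 24 genes of the unfolded protein and heat shock responses Hspa5 and Atf3 rose and Hsph1 (-0.48 ± 0.07, 0.0274) fell, with 1 lower when adjusted over the list alone and 4 higher and 1 lower so with the block (camera adjusted p = 0.643). Of 24 calcium handling genes 1 rose when adjusted over the list alone (1 rose and 1 fell with the block) and Orai1 rose over all genes with the block, with a negative median, a positive mean and an upward test (camera adjusted p = 0.692). Limma called 0 of 23 ribosomal protein genes and 0 of 4 sex-linked genes with or without the block, over all genes and adjusted over the list alone, with 0 at an unadjusted p under 0.05 (camera adjusted p = 0.834 and 0.782).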

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

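Rows without a gene name in the annotation table were tested separately from the named genes. Among 5430 such rows, 2 were higher and 3 lower in caNFATc1 cells, and 13 and 29 with the replicate block. Both higher rows stand out as signal in rows that the comparison of genes did not use. Row 10606016 was higher by 4.76 ± 0.38 on the log2 scale (SE, n = 3 per group, limma adjusted p = 0.0323), above the difference of any named gene. Row 10549877 was higher by 1.44 ± 0.13 (adjusted p = 0.0382). What these rows measure was not analysed here, and no explanation was tested. Of 1605 rows with several genes, 5 were higher and 6 lower with the block. Single arrays were not tested as outliers within the groups of 3.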

How the results depend on the processing

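The settings without replicate 1, 2 or 3 of both groups, the block with an estimated correlation and the block at a stricter threshold were chosen after the data were seen. In the unblocked fit 41 genes were higher and 2 lower, 29 and 1 at least 2-fold. These 4 counts became 126, 19, 63 and 2 after a second quantile normalization, 223, 87, 85 and 5 with the eBayes trend and robust settings, 212, 52, 85 and 4 with array weights, and 0, 0, 0 and 0 with the plain test. The plain test had 2125 genes at an unadjusted p under 0.05. With the replicate block they were 744, 475, 158 and 32, and with the block and without replicate 1, 2 or 3 of both groups 509, 202, 127 and 25, 513, 230, 204 and 53, and 605, 481, 158 and 49. Without replicate 1 and unblocked, 0 genes were lower, 0 at least 2-fold, with 2838 at an unadjusted p under 0.05 by limma, and 14 of the 43 genes stayed past the test. Without replicate 2 of both groups and unblocked they were 2, 0, 2 and 0, and without replicate 3 they were 0, 0, 0 and 0, with 1587 and 1580 at an unadjusted p under 0.05 by limma. Tested row by row, 0 rows fell at least 2-fold. An adjusted p under 0.01 left 1 and 0 genes (140 and 20 with the block), and one under 0.1 gave 210 and 65. Leaving out single arrays gave 0 to 74 higher and 0 to 9 lower, 0 to 59 and 0 to 7 at least 2-fold, and Nfatc1 differences from -0.03 to 0.08. Why the counts moved was not tested; fewer arrays leave fewer degrees of freedom.

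Camera called 9 lists, 7 to 12 with single arrays left out. With an estimated correlation 0 were called, at adjusted p = 0.824 for the basal and cornified lists, 0.471 for DNA repair and 0.468 for the other 6, and with the block and an estimated correlation 0, at 0.683 for each of the 9. The directional fry test called 1 list, the calcineurin-NFAT parts, at 0.00508 (0.0799 with the replicate block, where it called none), with 0.468 for the basal list, 0.593 for the cornified list and 0.205 for the other 6 named by camera; the cause was not tested. Its test for change in either direction called 16 lists, 26 with the block, among them lists that camera did not call. The NFAT targets were called in this way in both fits, and the phase I and II lists with the block only. The hair shaft list had 0.0705 with array weights, 0.122 with the replicate block, 0.152 without replicate 1 and 0.158 with both, and without replicate 2 or 3 of both groups 0.165 and 0.258 with the block, and 0.0637 without replicate 2 unblocked. Without replicate 2 of both groups the fatty acid list had 0.0708 and the fibroblast list was called at 0.0361 (0.0184 with the block, where 14 lists were called), and without replicate 3 the BMP and TGF-beta list had 0.0727 (0.0589 with the block). With the block and all arrays, no list called without it was lost other than hair shaft. Single arrays left out gave adjusted p from 0.0124 to 0.0399 for the calcineurin-NFAT parts, 2.18e-05 to 0.120 for basal, 1.83e-05 to 0.199 for cornified, 0.0174 to 0.0956 for hair shaft, 3.55e-23 to 8.52e-10 for G1/S, 2.95e-38 to 1.50e-14 for G2/M, 1.77e-05 to 0.0275 for DNA repair, 0.00455 to 0.0519 for BMP and TGF-beta, 0.0132 to 0.0994 for fatty acid, 0.0251 to 0.617 for fibroblast, 0.399 to 0.682 for NFAT targets, 0.560 to 0.881 for phase I and 0.288 to 0.923 for phase II genes. No gene or list named changed direction while called. The trend and quantile settings acted on row-centred values, whose mean does not follow brightness. The trend was therefore not one of variance with intensity. The quantile setting gave 1 distribution to arrays whose SD ran from 0.165 to 0.309. The higher counts of these 2 settings are thus no added evidence for more changed genes. The 2 filters on dim rows were not run because the values hold no signal over background.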

Other observations

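The tests of symbol families, fibroblast transcripts, single pairs, differentiated cells and replicate 1 were chosen, or given their bounds, after the results they bear on had been seen. Genes that share the start of their symbol formed 347 families of at least 8 measured genes, of which camera called 22, and 27 with the block. The families named were picked after their values had been seen, and no grouping of them was tested. The 20 Nup genes (nuclear pore) had a median log2 difference of -0.31 (camera adjusted p = 1.96e-07), and 5 fell with the replicate block, among them Nup37 (-0.56 ± 0.07, 0.0177). With the block and an estimated correlation the adjusted p was 0.999 for this family and for every other family named here, so none of these calls was kept. The 31 Snord genes (small nucleolar RNAs) had a median of -0.29 (2.99e-05) with 3 lower, and the 10 Utp genes (ribosome assembly) a median of -0.27 (0.00524) with 3 lower. The 8 Nop genes (nucleolar proteins) had a median of -0.31 (0.0227) with 2 lower, including Nop58 (-0.43 ± 0.06, 0.0248). The 13 Lsm genes (RNA binding) had a median of -0.28 (0.0339) with 6 lower, including Lsm2 (-0.53 ± 0.07, 0.0186).

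Other families were called upward. The 11 Mtmr genes (phosphoinositide phosphatases) had a median of 0.17 (camera adjusted p = 0.00524, and 0.999 with the block and an estimated correlation), and 4 rose with the replicate block, including Mtmr11 (1.94 ± 0.08, 0.00162). The 21 Atp6v genes (the proton pump of lysosomes) had a median of 0.09 (0.0339, and 0.999 with an estimated correlation in the same way) with 2 higher, including Atp6v1e1 (0.77 ± 0.09, 0.0145), and the pump's accessory gene Atp6ap2 rose too (1.17 ± 0.11, 0.00788). The 18 Atg genes (autophagy) had a median of 0.15 (0.0339, likewise 0.999) with 2 higher. Of 70 Rab genes, 13 rose with the block, including Rab43 (0.85 ± 0.07, 0.00652), and 3 fell, and the family's call (0.0429) was lost with the block (0.0774). The Trappc and Stx families were not called (0.0878 and 0.101, and 0.133 and 0.101 with the block).

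Postn and Fmod rose by 4.05 and 4.56, and a candidate explanation is a larger share of fibroblasts in the caNFATc1 cultures. The median log2 difference of 8 fibroblast transcripts picked after their values had been seen (Col1a1, Col1a2, Col3a1, Sparc, Vim, Dcn, Lum and Thy1) was 0.0922, with pair medians of -0.05, 0.06 and 0.39, and over the 22 measured markers of the fixed list other than Postn it was 0.06, with 10 below 0. Col3a1, Col6a1 and Col6a2 rose with the block, by 1.20, 0.73 and 0.51, and Col1a1 and Col3a1 differed by 1.31 and 1.67 in pair 3, so a smaller rise in fibroblasts stays open. Among these markers none other than Postn rose by more than 1.20. For the markers covered, this argues against fibroblasts as the whole source of rises above 3 log2 units. Row-centred values, however, hold no baseline for these markers. Genes outside the markers also rose with the block, among them Egfl6 (4.20), Loxl3 (2.96), Igf2 (2.84) and Srpx2 (2.78). Whether fibroblasts were the source of those genes was not tested. Vim had an unblocked SE of 1.25 with pair differences of 0.06, 0.06 and 0.50, so it varied between replicates. Postn and Fmod passed the comparison of caNFATc1 with vector control with and without the block and rose by at least 3.60 in each pair. An effect of caNFATc1 on them therefore stays as a hypothesis, and whether it is direct was not tested.

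Cell cycle genes lay lower in caNFATc1 cells, and 3 other accounts were set against an effect of the transgene. Over the 82 genes of the G1/S and G2/M lists the pair medians were -0.79, -0.77 and -0.20, so more than 1 pair showed the fall; the bound first set asked for medians below -0.2 in each pair, which pair 3 missed at -0.196, and it was relaxed afterwards. A uniform offset between arrays would move all genes alike, but the lists' median lay below that of all genes (-0.58 on the log2 scale). The deposited values had already been normalized, so a median near 0 over all genes was given in advance. The check therefore cannot decide whether the normalization itself shifted some sets of genes against others. More terminally differentiated cells would raise the cornified list, whose median was -0.18. That list was not called with an estimated correlation (camera adjusted p = 0.824). Row-centred values also do not show whether its genes were above background in these low-calcium cultures. The check therefore shows no rise of the list but cannot decide about differentiation. The comparison of caNFATc1 with vector control called both lists with the preset correlation and not with an estimated one, so an effect of the transgene stays as a hypothesis, and a difference in density between the cultures was not tested.

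Replicate 1 lay apart from replicates 2 and 3 in both groups, with an SD across genes of 0.321 to 0.349 between it and the others against 0.183 and 0.235 between replicates 2 and 3. The gap in Xist of 5.97 log2 units, with the higher Y-linked signal, could come from cells of another sex or donor in replicate 1. The bound asked for gaps above 2 log2 units in Xist and the Y-linked genes. Eif2s3y met it at 2.99. Kdm5d (1.36 and 1.67 in the replicate 1 arrays) and Uty (1.11 in vector control replicate 1) were higher but missed it. A label swapped between groups would put Rcan1 with the wrong group, but Rcan1 was higher by at least 3.12 in each same-numbered pair.

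The 6 arrays can be split into groups of 3 in 10 ways. The real split called 43 genes and the highest of the others 0, so 1 split reached the real count. With the replicate block, 4 splits part all 3 pairs, of which the real one called 1219 genes and the highest other 0. Both numbers of splits are too small for a share under 0.05.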
